A study of Homo sapiens with 6 samples.

How the data were processed

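The series holds RNA sequencing of 6 libraries, 3 of parental MDA-MB-231 and 3 of Pep2-E3 cells, grouped by their titles and genotype labels. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, which does not mark strand, and per the series' design text they were sequenced on an Illumina instrument. The submitters' processing notes name HISAT2 version 2, Bowtie2 version 2.2.3 and HTSeq version 0.6.0. The same notes give the genome build as mm8, a mouse build, whereas the deposited tables list human Ensembl gene identifiers. All 30099 identifiers are in GENCODE release 29 (GRCh38), whose coordinates are used here.

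The authors deposited 1 table per library with a gene identifier and an FPKM value, in the same gene order in each. FPKM multiplied by the length of the union of a gene's exons in GENCODE release 29 and by the library total gave a whole number of fragments, within 0.001, for 100% of the 180594 values, with a largest distance of 0.00016, and the recovered fragments of each library summed to the total used for scaling. The depth was 17154511 to 18206694 fragments per library, a ratio of 1.06 between the deepest and the shallowest. In these libraries 1 fragment in a gene of 2 kb is worth between 0.0275 and 0.0291 FPKM. Intervals or limits from such counts would cover counting error only. No gene is listed at 0 in all 6 libraries. Symbols came from a current gene name table for 29899 identifiers and from GENCODE for the other 200.

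The design written before the data were examined assumed fragment counts and named a negative binomial count test for that case, with limma as the test for FPKM. Because the deposited unit is FPKM, the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with the group as the only term, for the 14235 genes with a mean FPKM of at least 0.5 over the 6 libraries, and with Benjamini-Hochberg adjustment at 0.05. A log2 fold change is on the log2(FPKM + 1) scale and comes with its standard error (SE), and means of FPKM come with the standard deviation (SD) of 3 libraries. Folds are ratios of mean FPKM. The 49 gene lists were fixed before the data were examined. Members of a list that reached the filter on mean FPKM are called measured. For the 44 lists with at least 5 tested members, camera with a preset correlation of 0.01 compared each list with all other genes on log2(FPKM + 1), with adjustment over the lists. Camera with an estimated correlation and fry were run beside it.

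Genes were named by a rule fixed before the data were examined. It takes the 10 largest and 10 smallest log2 fold changes among genes that passed, had a symbol, a mean of at least 5 CPM in the higher group and no overlap of the groups. Chance alone gives no overlap in 10% of genes with 3 against 3. The rule adds the 5 smallest p-values in each direction, for each list called by camera the 4 smallest p-values among members changed in its direction and 2 changed against it, for other lists 2 members if they passed, and 10 genes chosen by name. This gave 139 tested genes, and CDH1, which did not reach the filter. The text and the figures leave out some of the genes that the rule chose.

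The test was checked on simulated data with known changes, drawn from the real libraries' means and totals. All simulated genes had the same dispersion in both groups, the median of the parental libraries, and no GC trend. Among 14273 simulated genes, limma-trend recovered 11 of 50 genes changed 1.2-fold, 38 of 50 changed 1.5-fold, 48 of 49 changed 2-fold and 50 of 50 changed 4-fold, with 13 false calls among 160. The real Pep2-E3 libraries lay further apart than the parental ones. The mean chi-square per gene of recovered fragments between them was 4.07 to 19.3, against 2.63 to 3.78 between parental libraries. The simulated rates therefore need not hold for the real comparison. Alternatives were RLE size factors, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, pseudocounts of 0.1 and 5, leaving out mitochondrial genes and the 50 most abundant genes, limma-voom on the recovered fragments, the replicate number as a block, and leaving out each library. A correction of each library for GC content and exon length (natural splines with 5 degrees of freedom each), leaving out genes in chromosome blocks, and the correction with Pep2-E3 replicate 1 left out were chosen after seeing the data.

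GC content was taken from the longest transcript of each gene and was known for 100% of tested genes. Deviations of a library were taken from the mean of the other libraries of its group. For chromosome blocks, limma-voom log2 ratios of 10806 genes with a mean of at least 5 CPM were ordered by position, centred on their median, limited to 1 in size and smoothed with a running median over 41 genes. Blocks of at least 20 genes were kept where it exceeded 0.314 in size, the limit reached in 1% of 1000 permuted gene orders. Sequence shared between genes was measured as the share of words of 50 bases in a gene's longest transcript that occur in transcripts of other genes on either strand, and exon overlap from the annotation. Between replicates, the mean chi-square per gene of recovered fragments ranged from 2.63 to 19.3, so no pair of libraries was alike within sampling noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.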

Results

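RNA from MDA-MB-231, an established human breast cancer cell line, was compared by RNA sequencing with RNA from cells of the same background that the labels call Pep2-E3. The labels mark the parental cells as the control and give Pep-E3 as the genotype of the other cells, and they do not say what that name stands for. There were 3 libraries per group, and the question was how the transcriptomes of both cell populations differ. Each library lists FPKM values (fragments per kilobase of exon, scaled to library depth) for 30099 genes. The values resolved into whole fragments, which gave 18159433, 18206694 and 17538266 fragments in MDA-MB-231 replicates 1, 2 and 3 and 17161711, 17289162 and 17154511 in Pep2-E3 replicates 1, 2 and 3. No label says that the replicates are separate cultures, so p-values measure the spread between these libraries, which may be technical.

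SPANXB1, a cancer-testis antigen gene, had the largest log2 fold change on the log2(FPKM + 1) scale, from 43.1 ± 2.97 in MDA-MB-231 to 596 ± 21.3 FPKM in Pep2-E3 (SD, n = 3 per group). SLC14A1, a urea transporter, rose from 0.244 to 13.2 FPKM, and MAGEA6, another cancer-testis antigen gene, rose from 0.438 to 11.3 FPKM. The secreted metalloprotease ADAMTS1 rose 12.2-fold and the calcium-binding protein CALB2 6.95-fold. In the other direction, RAP1GAP2, a GTPase-activating protein for RAP1, fell 8.17-fold, from 11.2 ± 0.153 in MDA-MB-231 to 1.38 ± 0.173 FPKM in Pep2-E3. The dynamin DNM1, the actin-associated LIMCH1 and the matrix protein MATN2 fell 4.18-fold, 3.47-fold and 3.63-fold.

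The other genes named for large rises were the actin-bundling LCP1 (4.19-fold), the nucleosome-binding HMGN5 (0.154 to 2.98 FPKM), the surface receptor SLAMF7 (3.86-fold), the linker histone H1-2 (3.33-fold) and the protease inhibitor SERPINB2 (0.0608 to 2.19 FPKM). SERPINB2 rested on a mean of 3 fragments per parental library. The other large falls were in the NOTCH-related repressor HES7 (5.64-fold), the vesicle GTPase RAB3A (3.06 to 0.469 FPKM), the long noncoding RNA CASC8 (4.46 to 0.993 FPKM), the activin antagonist FST (2.75-fold) and the noncoding KLC1-AS1 (3.63-fold). KISS1, a metastasis suppressor gene, had a smaller but very even fall from 158 ± 2.55 in MDA-MB-231 to 84.1 ± 1.80 FPKM in Pep2-E3. In limma's test with Benjamini-Hochberg adjustment, adjusted p was 1.51e-06 for SPANXB1, 6.22e-06 for SLC14A1, 6.22e-06 for ADAMTS1, 1.06e-05 for MAGEA6, 6.27e-05 for LCP1, 1.53e-05 for RAP1GAP2, 2.50e-05 for MATN2, 5.87e-05 for DNM1, 6.27e-05 for LIMCH1 and 0.000100 for KISS1. In each of these genes all 3 Pep2-E3 values lay on the same side of all 3 parental values.

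In GRCh38 coordinates, SPANXB1 (ENSG00000227234) lies on chromosome X, 141002591 to 141003706, SLC14A1 (ENSG00000141469) on chromosome 18, 45687025 to 45752520, MAGEA6 (ENSG00000197172) on chromosome X, 152766136 to 152769747, ADAMTS1 (ENSG00000154734) on chromosome 21, 26835747 to 26845409 and CALB2 (ENSG00000172137) on chromosome 16, 71358713 to 71390438. RAP1GAP2 (ENSG00000132359) lies on chromosome 17, 2755705 to 3037739, DNM1 (ENSG00000106976) on chromosome 9, 128191655 to 128255248, LIMCH1 (ENSG00000064042) on chromosome 4, 41359607 to 41700044, MATN2 (ENSG00000132561) on chromosome 8, 97868840 to 98036716 and KISS1 (ENSG00000170498) on chromosome 1, 204190341 to 204196486. Of the words of 50 bases in the longest MAGEA6 transcript, 56.6% also occur in transcripts of other genes, mostly MAGEA3, and in SPANXB1 21.7% occur in other genes, mostly SPANXA1. The values of both genes may therefore be split between copies.

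**Figure D1:**
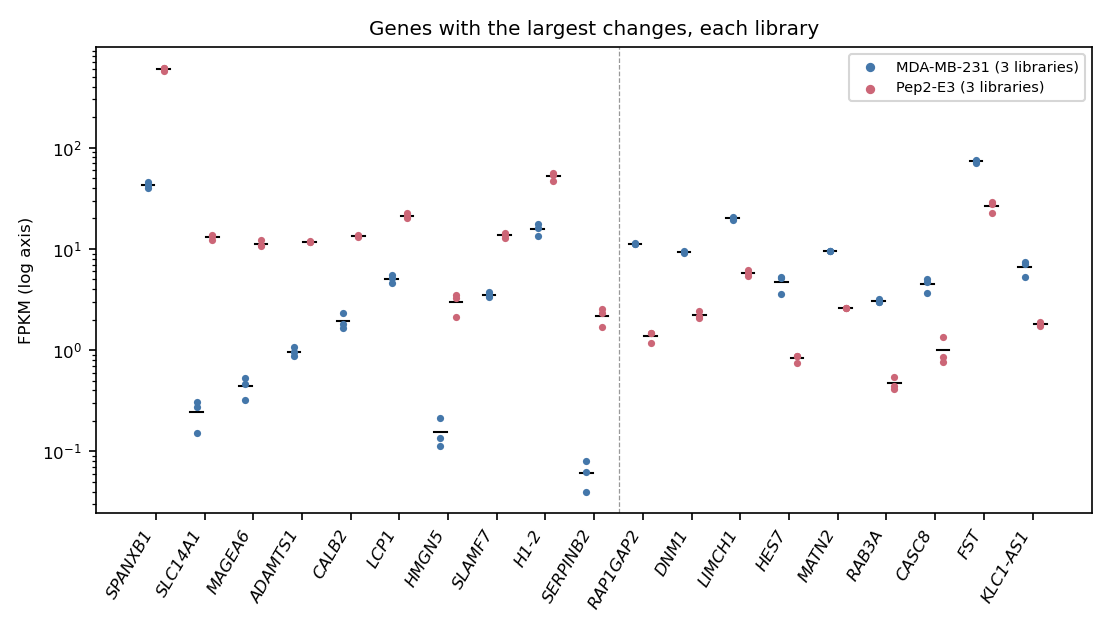
FPKM in each library (points, log axis) for the 10 genes with the largest rise (left of the dashed line) and 9 of the 10 with the largest fall (right) that the naming rule chose, with the mean of each group of 3 libraries as a bar. In each of these genes the groups do not overlap.

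Across the 14235 genes tested, 4383 (30.8%) differed between the groups, 2072 of them higher and 2311 lower in Pep2-E3 (limma-trend on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). Of these, 191 changed at least 2-fold on that scale, 78 upward and 113 downward. The scale understates the change of low genes, and the number at or above 2-fold was 557 with a pseudocount of 0.1, 25 with a pseudocount of 5 and 621 with limma-voom on the recovered fragments. In 46 of the 191 genes both groups had a mean under 20 fragments per library. The number of changed genes was 2699 without MDA-MB-231 replicate 1, 2474 without MDA-MB-231 replicate 2 and 2893 without MDA-MB-231 replicate 3. Without these libraries in turn, 1284, 1185 and 1365 genes were higher and 1415, 1289 and 1528 lower. Without Pep2-E3 replicate 2 the number of changed genes was 2991. The counts of changed list members given below are to be read beside the 30.8% of all tested genes that changed.

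**Figure D2:**
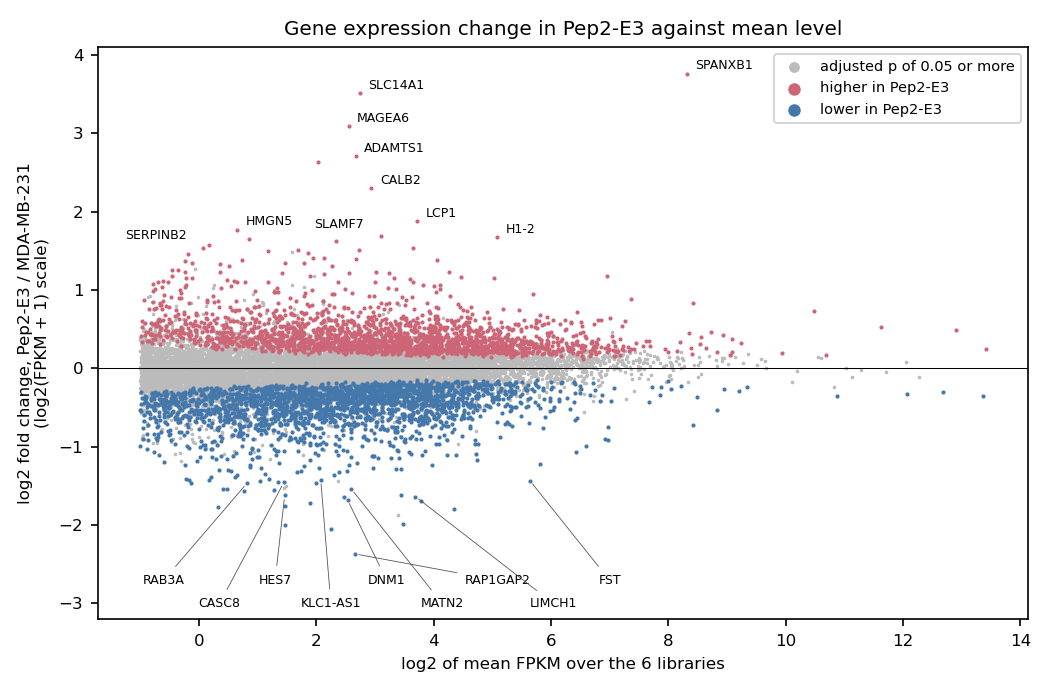
Log2 fold change between Pep2-E3 and MDA-MB-231 on the log2(FPKM + 1) scale (vertical axis) against the log2 of the mean FPKM over the 6 libraries (horizontal axis), 1 point per tested gene. The 2072 genes higher in Pep2-E3 and the 2311 lower are coloured, and the genes with the largest changes under the naming rule that the text names are labelled.

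The list of G1/S and DNA replication genes and the list named replication-dependent histones were called upward in Pep2-E3. Of the G1/S and DNA replication list, 16 of 25 measured members were higher and 0 lower (18 and 1 adjusted over the list alone), among them the cyclin CCNE1, the DNA methylation factor UHRF1, the replicative helicase subunit MCM6 and its partner GINS2, with log2 fold changes (± SE) of 0.66 ± 0.06, 0.53 ± 0.06, 0.47 ± 0.06 and 0.64 ± 0.07. Of the replication-dependent histones, 7 of 9 measured members were higher and 0 lower (7 and 0 adjusted over the list alone), among them H1-2 (1.68 ± 0.11), H2BC12 (1.18 ± 0.08), H2AC6 (1.09 ± 0.11) and H2BC21 (0.76 ± 0.07). The histone genes H1-4 (0.09 ± 0.16) and H4C3 (-0.005 ± 0.228) did not pass (limma adjusted p = 0.71 and 0.99). Whether the rise of the histone genes is tied to DNA replication was not tested. In H2BC12, 74.1% of its transcript's words of 50 bases also occur in other genes. The G2/M list was not called: 2 of 25 measured members were higher and 1 lower (2 and 0 adjusted over the list alone), FOXM1 at 0.39 ± 0.06 and CCNB1 at 0.22 ± 0.05. The proliferation marker MKI67 was 53.5 ± 2.62 in MDA-MB-231 and 56.6 ± 6.54 FPKM in Pep2-E3 (adjusted p = 0.540). The camera test of each list against all other genes gave an adjusted p of 4.09e-05 for G1/S and DNA replication, 0.000168 for histones and 0.899 for G2/M. For the first 2 of these lists the call was lost with adjusted p = 0.587 and adjusted p = 0.289 with an estimated correlation.

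The lists of heat shock proteins and proteasome subunits were called upward in Pep2-E3. Of the heat shock proteins, 10 of 18 measured members were higher and 1 lower (11 and 1 adjusted over the list alone). The small chaperone HSPB8 rose 3.91-fold, the constitutive HSP70 gene HSPA8 rose from 246 ± 1.83 in MDA-MB-231 to 438 ± 24.6 FPKM in Pep2-E3, and the co-chaperones DNAJA1 and DNAJB1 rose by 0.56 ± 0.06 and 0.51 ± 0.06 on the log2 scale (± SE), whereas the HSP90 gene HSP90AA1 fell (-0.37 ± 0.04). Of the proteasome subunits, 13 of 29 measured members were higher and 1 lower (19 and 1 adjusted over the list alone), with rises in PSMA3 (0.52 ± 0.07), PSMC6 (0.39 ± 0.05), PSMA7 (0.35 ± 0.06) and the assembly factor POMP (0.25 ± 0.04). PSMC1 was lower (-0.32 ± 0.06), but 82.1% of its exon bases overlap exons of NRDE2 on the opposite strand. Autophagy and lysosome genes also moved up on balance: 14 of 28 measured members were higher and 5 lower (15 and 6 adjusted over the list alone). The lysosomal sialidase NEU1 rose 2.11-fold, the membrane protein LAMP1 (0.57 ± 0.05) and the cathepsin CTSL (0.53 ± 0.05) rose, and the autophagy-initiating kinase ULK1 (-0.47 ± 0.07) and GABARAPL1 (-0.47 ± 0.08) fell. Adjusted p in the camera test was 0.000983 for heat shock proteins, 0.000170 for the proteasome and 0.00234 for autophagy and lysosome. None of these calls held with an estimated correlation (adjusted p = 0.507, adjusted p = 0.649 and adjusted p = 0.649 with an estimated correlation, in that order).

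The lists of ribosome biogenesis and ribosomal proteins were also called upward. In the list of MYC targets and ribosome biogenesis, 10 of 24 measured members were higher and 2 lower (12 and 3 adjusted over the list alone). The ornithine decarboxylase ODC1 (0.57 ± 0.06) and the nucleolar genes NOP16 (0.35 ± 0.05), RRP9 (0.40 ± 0.06) and PES1 (0.35 ± 0.07) rose, and CAD (-0.23 ± 0.06) and GNL3 (-0.18 ± 0.05) fell. MYC itself was 97.3 ± 3.60 in MDA-MB-231 and 83.1 ± 7.11 FPKM in Pep2-E3, with an adjusted p of 0.0444. Among ribosomal proteins 7 of 40 measured members were higher and 4 lower (7 and 4 adjusted over the list alone): RPL5 (0.45 ± 0.05), RPS20 (0.30 ± 0.06), RPL10A (0.38 ± 0.07) and RPS7 (0.23 ± 0.06) rose, and RPL9 (-0.49 ± 0.06) and RPL8 (-0.29 ± 0.07) fell. Ribosomal protein genes have many processed pseudogenes, and 28.5% of the words of RPL10A and 26.6% of those of RPL9 also occur in other genes. Camera gave an adjusted p of 0.0126 and 0.0169 for these lists. With an estimated correlation the values were adjusted p = 0.649 and adjusted p = 0.933. Unfolded protein and amino acid response genes went both ways, with 7 higher and 5 lower of 22 measured (8 and 5 adjusted over the list alone). The transcription factor ATF4 (0.62 ± 0.07) and the phosphatase subunit PPP1R15A (0.59 ± 0.07) were higher. Of the E3 ubiquitin ligases and adaptors, 4 of 35 measured members were higher and 11 lower (6 and 14 adjusted over the list alone). KEAP1, the adaptor that targets NRF2 for degradation, rose from 18.7 to 28.2 FPKM and UBE3A fell from 7.08 to 3.35 FPKM. STUB1, a chaperone-linked ligase, was 16.1 ± 1.04 in MDA-MB-231 and 16.8 ± 0.818 FPKM in Pep2-E3 (adjusted p = 0.487), and 42.6% of its exon bases overlap JMJD8 on the opposite strand.

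The list of NF-kB and inflammatory cytokines was called upward. In it, 13 of 22 measured members were higher and 1 lower (13 and 2 adjusted over the list alone). The cytokine IL6 rose from 1.39 ± 0.111 in MDA-MB-231 to 3.72 ± 0.780 FPKM in Pep2-E3, the chemokine CXCL2 rose 1.80-fold, the cytokine LIF 1.70-fold and the adhesion molecule ICAM1 1.53-fold, while IL1B was lower (log2 fold change -0.41 ± 0.09, SE). Of the exon bases of ICAM1 and IL6, 26.9% and 25% overlap genes on the opposite strand. Camera gave an adjusted p of 0.000983 for this list, and adjusted p = 0.289 with an estimated correlation. Of the interferon-stimulated genes, 3 of 22 measured members were higher and 8 lower (3 and 9 adjusted over the list alone), with falls in OASL (2.33-fold) and DDX60 (2.38-fold), and camera did not call the list (adjusted p = 0.167), though it did without the genes in chromosome blocks described below, a setting chosen after seeing the data (adjusted p = 0.00968). With all tested genes the list had adjusted p = 0.649 with an estimated correlation. MHC class I genes had 4 higher and 0 lower of 16 measured (4 and 0 adjusted over the list alone): HLA-B rose 1.48-fold and B2M, the light chain of class I molecules, 1.25-fold (camera adjusted p = 0.0551). Of the exon bases of HLA-B, 23.5% overlap a gene on the opposite strand. Camera called the MHC class I list with RLE size factors (adjusted p = 0.0446), without a filter (0.00256), with the filter of 1 CPM (0.0431), without mitochondrial and the 50 most abundant genes (0.0448) and without Pep2-E3 replicate 2 (0.0374). With all tested genes and libraries it had adjusted p = 0.507 with an estimated correlation. Of the 6 MHC class II genes with values, 2 reached the filter, and 1 of these 2, HLA-DMA, was lower (-0.55 ± 0.08). Among immune checkpoint ligands, 1 of 9 measured members was higher and 3 lower (1 and 3 adjusted over the list alone). CD274, which encodes PD-L1, fell from 20.5 ± 1.61 in MDA-MB-231 to 12.1 ± 1.42 FPKM in Pep2-E3 (adjusted p = 0.00281), and PDCD1LG2, which encodes PD-L2, fell 1.82-fold.

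The hypoxia and glycolysis lists were called downward in Pep2-E3. In the hypoxia list, 1 of 21 measured members was higher and 12 lower (2 and 12 adjusted over the list alone). The stress gene NDRG1, the carbonic anhydrase CA12, the mitophagy gene BNIP3 and the pyruvate dehydrogenase kinase PDK1 fell 2.07-fold, 3.48-fold, 1.65-fold and 2.13-fold, and the angiogenic factor VEGFA moved against the list, from 5.92 ± 0.118 in MDA-MB-231 to 9.59 ± 0.280 FPKM in Pep2-E3. In the glycolysis list, 0 of 16 measured members were higher and 6 lower (1 and 8 adjusted over the list alone): the hexokinase HK2 (-0.62 ± 0.06), the aldolase ALDOC (-0.86 ± 0.10), PGK1 (-0.29 ± 0.04) and the lactate dehydrogenase LDHA (-0.24 ± 0.04) fell. Camera gave an adjusted p of 0.00489 for hypoxia and 0.0257 for glycolysis. With an estimated correlation these became adjusted p = 0.507 and adjusted p = 0.649.

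The remaining metabolic lists did not pass camera. Of these lists, fry called cholesterol synthesis downward (adjusted p = 0.00147). It called serine and one-carbon metabolism (adjusted p = 0.0131) and NRF2 antioxidant genes (adjusted p = 0.0307) upward. Camera with an estimated correlation gave adjusted p = 0.649 for each of the lists that fry called here. Nuclear-encoded oxidative phosphorylation genes showed 2 higher and 2 lower of 26 measured (1 and 2 adjusted over the list alone), with UQCRC1 (0.61 ± 0.05) up and COX6C (-0.35 ± 0.06) down. Mitochondrially encoded genes moved apart, with 3 higher and 3 lower of 13 measured (3 and 3 adjusted over the list alone): MT-CO3 rose from 6349 ± 108 in MDA-MB-231 to 8939 ± 348 FPKM in Pep2-E3 and MT-ND1 by 0.53 ± 0.06 on the log2 scale (SE). Without a filter on low values, adjusted p was 0.284 for MT-CO3 and 0.0775 for MT-ND1. Of cholesterol synthesis genes 2 of 24 measured members were higher and 8 lower (2 and 8 adjusted over the list alone), the falls including the squalene synthase FDFT1 (-0.53 ± 0.05). Fatty acid synthesis and storage had 2 higher and 3 lower of 18 measured (2 and 3 adjusted over the list alone), with DGAT1 (-0.70 ± 0.08) down and the transcription factor SREBF1 (0.40 ± 0.05) up. Fatty acid oxidation had 1 higher and 4 lower of 16 measured (2 and 5 adjusted over the list alone), with falls in ACADVL (-0.53 ± 0.06) and ACADS (-0.30 ± 0.05). Serine and one-carbon metabolism had 3 higher and 0 lower of 11 measured (3 and 0 adjusted over the list alone), with rises in the serine synthesis enzyme PHGDH (0.64 ± 0.08) and the folate enzyme MTHFD1 (0.51 ± 0.04). In the NRF2 antioxidant list, 6 of 16 measured members were higher and 1 lower (7 and 1 adjusted over the list alone). TXNRD1, the cytosolic thioredoxin reductase, fell from 158 ± 4.65 in MDA-MB-231 to 93.3 ± 1.52 FPKM in Pep2-E3, and the ferritin heavy chain FTH1 rose 1.66-fold. For FTH1, 78.7% of the transcript's words occur in other genes, and 56.6% of its exon bases overlap BEST1 on the opposite strand.

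**Figure D3:**
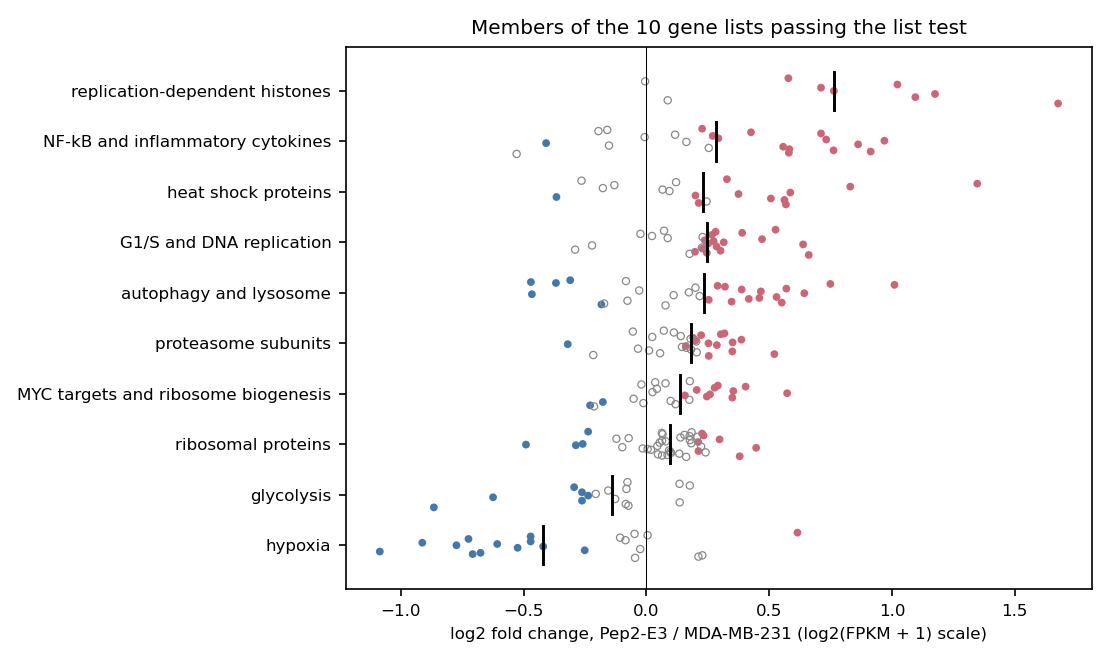
Log2 fold change between Pep2-E3 and MDA-MB-231 on the log2(FPKM + 1) scale for each measured member of the 10 lists with a camera adjusted p under 0.05. Filled points passed the test for the single gene (red higher, blue lower), open points did not, and the bar is the list's median, which runs from -0.42 for hypoxia to 0.76 for histones.

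Camera called none of the lists of cell identity markers, and fry called the basal and myoepithelial list upward (adjusted p = 0.0307). Among mesenchymal genes 2 of 11 measured members were higher and 1 lower (2 and 1 adjusted over the list alone): S100A4 rose from 6.55 to 12.4 FPKM and the transcription factor SNAI2 from 0.653 to 1.55 FPKM. Vimentin (VIM) was 174 ± 4.89 in MDA-MB-231 and 158 ± 5.82 FPKM in Pep2-E3 (adjusted p = 0.0639), and 52.6% of its exon bases overlap VIM-AS1 on the opposite strand. The epithelial list had 3 higher and 6 lower of 14 measured (4 and 7 adjusted over the list alone), with the tight junction gene CLDN4 down 1.60-fold and the keratin KRT18 up 1.43-fold. CDH1, which encodes E-cadherin, was near the limit of detection at 0.0361 ± 0.0268 FPKM in MDA-MB-231 and 0.0408 ± 0.00552 in Pep2-E3, from 12 and 13 fragments per group, and was not tested. The basal and myoepithelial list had 2 higher and 2 lower of 10 measured (2 and 2 adjusted over the list alone), where the integrin ITGB4 fell from 12.7 ± 0.163 in MDA-MB-231 to 6.15 ± 0.416 FPKM in Pep2-E3. Luminal and hormone receptor genes had 2 higher and 1 lower of 8 measured (2 and 1 adjusted over the list alone), with GATA3 (0.74 ± 0.11) up and ERBB3 (-0.58 ± 0.09) down. Stemness markers had 0 higher and 4 lower of 11 measured (0 and 4 adjusted over the list alone): CD24 (-0.53 ± 0.09) and NES (-0.41 ± 0.09) were lower, and CD44 was 63.3 ± 0.685 in MDA-MB-231 and 62.5 ± 2.79 FPKM in Pep2-E3 (adjusted p = 0.778). Members of this list, CD24 among them, need not rise with a stem-like state, so these counts do not show whether such a state changed. EGFR was 38.1 ± 1.88 in MDA-MB-231 and 41.8 ± 1.16 FPKM in Pep2-E3 (adjusted p = 0.104).

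Genes of the matrix and its proteases changed in both directions. Matrix proteases and inhibitors had 8 higher and 3 lower of 22 measured (8 and 4 adjusted over the list alone), with ADAMTS1 and SERPINB2 up. MMP1, an interstitial collagenase, fell from 1.32 ± 0.293 in MDA-MB-231 to 0.187 ± 0.134 FPKM in Pep2-E3 (adjusted p = 0.00319). Collagens, laminins and matrix glycoproteins had 4 higher and 5 lower of 19 measured (5 and 6 adjusted over the list alone): the collagen COL7A1 rose 3.67-fold and the proteoglycan HSPG2 fell 1.99-fold. Integrins had 2 higher and 3 lower of 12 measured (3 and 3 adjusted over the list alone), with ITGA3 (0.28 ± 0.06) up beside the fall of ITGB4. Of the genes linked to lung metastasis of MDA-MB-231 5 of 13 measured members were higher and 2 lower (7 and 2 adjusted over the list alone), KYNU rising 2.46-fold and NEDD9 falling from 2.08 to 0.386 FPKM. Of those linked to bone metastasis 1 of 6 measured members was higher and 4 lower (1 and 5 adjusted over the list alone), ADAMTS1 upward and the matricellular CCN2 downward. Migration and actin genes had 7 higher and 5 lower of 28 measured (7 and 5 adjusted over the list alone), with falls in TPM2 (-0.67 ± 0.05) and the focal adhesion kinase PTK2 (-0.55 ± 0.05). Angiogenesis genes had 4 higher and 6 lower of 15 measured (5 and 6 adjusted over the list alone), including VEGFA upward and FGF1 (-0.47 ± 0.07) downward.

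Signalling lists also had changed members in both directions, and camera called none of them. Since 30.8% of all tested genes changed, such counts alone do not set a list apart. TGF-beta targets had 4 higher and 3 lower of 18 measured (4 and 3 adjusted over the list alone), with CCN2 falling from 427 ± 8.08 in MDA-MB-231 to 258 ± 7.61 FPKM in Pep2-E3 and TGFBI (0.61 ± 0.08) rising. YAP/TAZ targets had 7 higher and 7 lower of 20 measured (7 and 8 adjusted over the list alone), including falls in CRIM1 (2.12-fold) and CCN2. WNT targets and components had 3 higher and 1 lower of 14 measured (3 and 1 adjusted over the list alone), with FZD8 (0.51 ± 0.09) up and the WNT antagonist DKK1 (-0.42 ± 0.11) down. The NOTCH list had 1 higher and 2 lower of 10 measured (1 and 2 adjusted over the list alone), where the ligand JAG2 fell 2.40-fold and the target HES1 rose 3.21-fold. In MAPK feedback and AP-1 genes, with 5 higher and 6 lower of 25 measured (5 and 8 adjusted over the list alone), IER3 rose 1.85-fold and the ERK phosphatase DUSP6 fell 2.00-fold, and 26.5% and 39.4% of their exon bases overlap genes on the opposite strand. The p53 targets had 4 higher and 2 lower of 17 measured (4 and 2 adjusted over the list alone): the death receptor TNFRSF10B (-0.32 ± 0.05) was lower and the cyclin-dependent kinase inhibitor CDKN1A (0.40 ± 0.06) higher. Apoptosis genes had 2 higher and 3 lower of 22 measured (1 and 1 adjusted over the list alone), with BAX (0.28 ± 0.06) up beside the fall of TNFRSF10B. Of the drug efflux transporters 0 of 9 measured members were higher and 1 lower (0 and 1 adjusted over the list alone), ABCA2 (2.42-fold).

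Most markers of other cell types had values under the filter of a mean of 0.5 FPKM. It was reached by 2 of 12 leukocyte, 1 of 11 fibroblast, 3 of 10 endothelial and 3 of 8 kidney and packaging line markers with values. Of the 2 measured leukocyte markers, LAPTM5 was higher (7.22 to 17.1 FPKM) and the other did not pass. Of the 3 measured endothelial markers, ESAM was higher (63.4 to 90.1 FPKM) and 2 did not pass, and the 1 measured fibroblast marker did not pass. These lists, the kidney and packaging line markers and MHC class II had fewer than 5 measured members and were not tested as lists. In the list of RNA quality and nuclear RNA, 5 of 11 measured members were higher and 0 lower (5 and 0 adjusted over the list alone), among them the small nucleolar RNA host genes SNHG8 (0.49 ± 0.08) and SNHG1 (0.33 ± 0.05), without passing camera (adjusted p = 0.309). Fry called this list upward (adjusted p = 0.0362), and camera with an estimated correlation gave adjusted p = 0.649.

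Of the 44 lists tested, camera with a preset correlation called 10, 8 upward and 2 downward, and the adjusted p of the other lists lay between 0.0551 and 0.999. In other splits of the 6 libraries into 3 and 3, which mix both cell populations, it called up to 6 lists although 0 genes were called. With an estimated correlation camera called 0 lists after adjustment and 3 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance without reference to other genes, called 24. Fry called 9 of the 10 lists that camera called. Beyond these it called basal, MHC class I, serine, amino acid response, NRF2, WNT, matrix protease, lung metastasis and RNA quality genes upward. It called interferon-stimulated, checkpoint ligand, cholesterol synthesis, YAP/TAZ, E3 ligase and drug efflux genes downward. The median, the mean and the camera direction differed in sign for mesenchymal, G2/M, p53 target, nuclear oxidative phosphorylation, fatty acid synthesis, integrin, migration and drug efflux genes, none of which camera called. Of these, fry called the drug efflux list (adjusted p = 0.0281).

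Some calls were lost when libraries were left out or settings changed, while the estimates kept their sign. The ribosomal protein list lost its call without MDA-MB-231 replicate 1 (adjusted p = 0.0675), MDA-MB-231 replicate 2 (0.115), Pep2-E3 replicate 1 (0.145) or Pep2-E3 replicate 2 (0.0530), and with the GC and length correction (0.290), with a mean log2 shift between 0.077 and 0.12 in these fits and 0.12 with all libraries and no correction. With the correction and without Pep2-E3 replicate 1 the shift was 0.046 (adjusted p = 0.509), and fry did not call this list either (adjusted p = 0.296). The list of MYC targets and ribosome biogenesis lost it without Pep2-E3 replicate 1 (0.0585), and with the correction as well (0.0771, shift 0.11 against 0.17), where camera called 8 lists. The glycolysis list lost it without MDA-MB-231 replicate 3 (0.0638), Pep2-E3 replicate 2 (0.0559) or Pep2-E3 replicate 3 (0.146), and with upper-quartile factors (0.0509), with a shift between -0.14 and -0.11 against -0.14. Of the 134 named genes that passed, 119 passed under each alternative in which they were tested. Without MDA-MB-231 replicate 1, DKK1 (0.0798), ITGA3 (0.0504), NES (0.0557), BAX (0.0556), CAD (0.0609), GNL3 (0.116), RPS7 (0.0638), RPL8 (0.0526) and MYC (0.0937) did not pass. Without MDA-MB-231 replicate 2 the same held for CCNB1 (0.0564), IL1B (0.0554), DKK1 (0.0930), NES (0.0677), CAD (0.0907), GNL3 (0.0509), RPS7 (0.0897) and MYC (0.106), and without MDA-MB-231 replicate 3 for IL1B (0.0568), DKK1 (0.0742), CAD (0.0656), GNL3 (0.110), RPS7 (0.0548), RPL8 (0.0628) and MYC (0.134). Without Pep2-E3 replicate 2, IL1B (0.0534), CAD (0.0766), GNL3 (0.0890), RPS7 (0.0899), RPL8 (0.0650) and MYC (0.126) did not pass, and without Pep2-E3 replicate 3, CAD (0.0528), GNL3 (0.0691) and MYC (0.0957) did not. With RLE size factors GNL3 (0.0543) and MYC (0.0674) did not pass, with upper-quartile factors CAD (0.0512), GNL3 (0.0733) and MYC (0.0871), without mitochondrial and the 50 most abundant genes MYC (0.0585), and without a filter DKK1 (0.0810), GNL3 (0.0553), MYC (0.0992), RPL8 (0.0946), RPL10A (0.0501) and RPS7 (0.0592). Values in parentheses are limma adjusted p for genes and camera adjusted p for lists. In these fits the log2 fold change of CAD lay between -0.25 and -0.20, that of GNL3 between -0.21 and -0.15 and that of MYC between -0.25 and -0.18, against -0.23, -0.18 and -0.23 with all libraries.

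Neighbouring genes on 5 chromosomes shifted together in Pep2-E3, a comparison chosen after the values were seen. In GRCh38 coordinates, genes were lower on chromosome 4 from 2843857 to 52038482 (89 of 96 genes, median ratio 0.68), chromosome 8 from 81701334 to 143023832 (123 of 136, 0.77), chromosome 12 from 76025447 to 113192368 (124 of 133, 0.75), chromosome 14 from 90396502 to 105499575 (73 of 80, 0.71) and chromosome 16 from 32103245 to 53504411 (21 of 22, 0.72). They were higher on chromosome 14 from 64914361 to 81221377 (77 of 82, 1.33). Each shift had the same sign in all 3 Pep2-E3 libraries. Of the genes named above, LIMCH1 and RPL9 lie in the chromosome 4 block, MATN2, CASC8, NDRG1, COX6C, PTK2 and MYC in the chromosome 8 block, TXNRD1 and DUSP6 in the chromosome 12 block, and KLC1-AS1, HSP90AA1 and JAG2 in the lower chromosome 14 block. All 13 were lower in Pep2-E3. Without the genes in the blocks, 3878 genes were called, 1969 higher and 1909 lower.

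**Figure D4:**
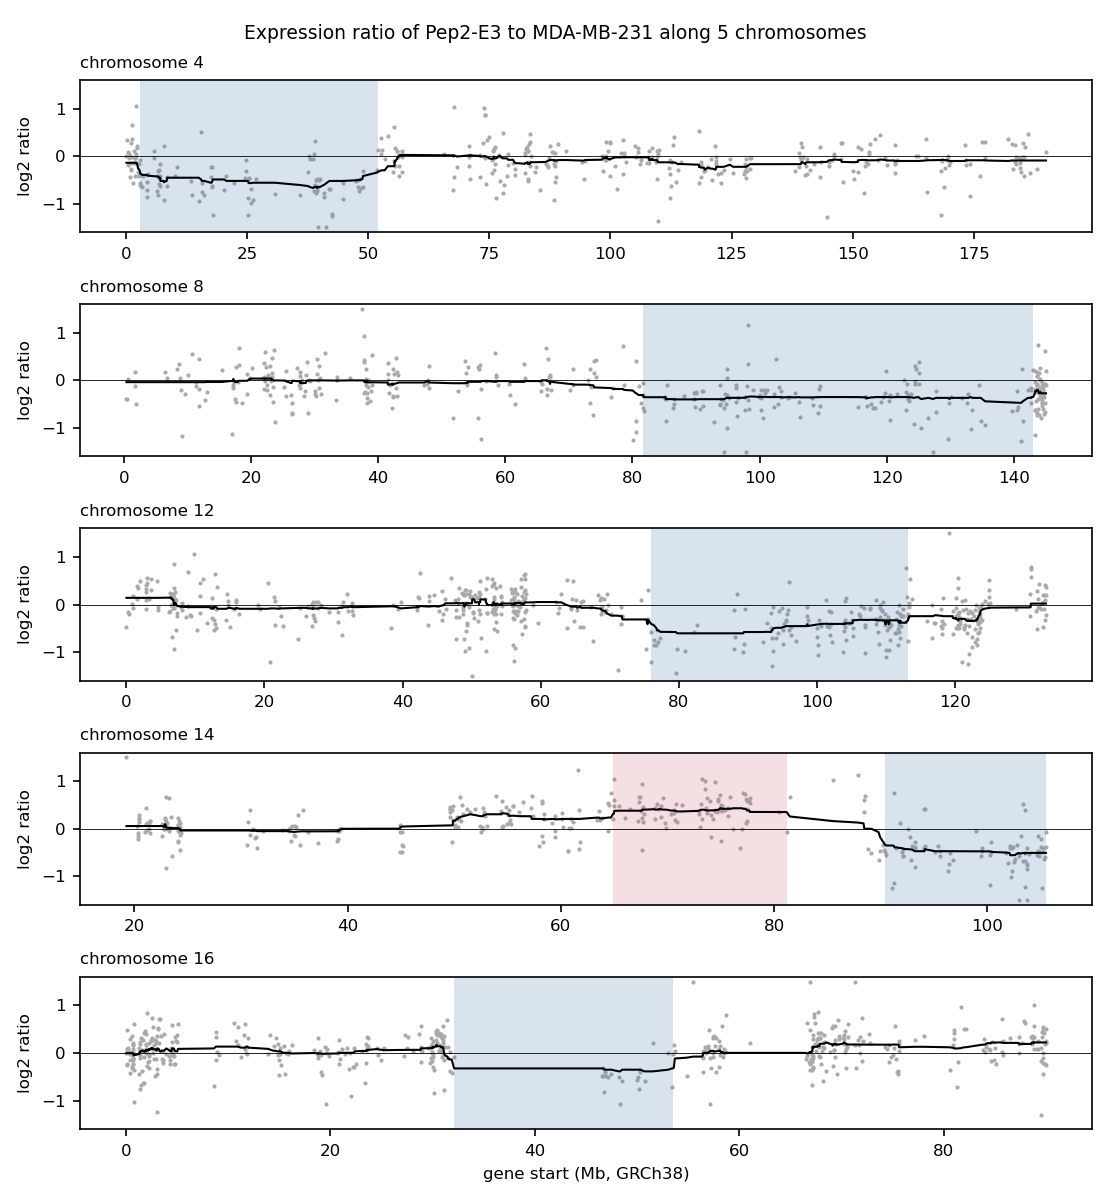
Log2 ratio of Pep2-E3 to MDA-MB-231 from limma-voom on recovered fragments, less the median of all genes (grey points, limited to 1.5 in size), and its running median over 41 genes (line) along 5 chromosomes by gene start in Mb of GRCh38. Shading marks the 5 blocks shifted down (blue) and the block shifted up (red).

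Pep2-E3 replicate 1 stood apart from the other libraries of its group along GC content. In the fifth of genes with the lowest GC content, its median lay at -0.31 on the log2 scale relative to the mean of the other 2 Pep2-E3 libraries, and 83.4% of these genes were lower in it than in both. In the fifth with the highest GC content its median was 0.11. Across genes, which are not independent replicates, Spearman's rho between GC content and its deviation was 0.59, and the fold changes of the group comparison had a rho of 0.19 with GC content, which was 0.01 without this library. The lists called in the comparison had median GC contents between 46.8% and 53.2%. Without this library 4857 genes were called, 2302 higher and 2555 lower, and with a GC and length correction 5360 were called. Among the genes named above, the correction moved VIM (log2 fold change -0.17, adjusted p = 0.0355) and EGFR (0.16, adjusted p = 0.0285) past the threshold and POMP (0.36, adjusted p = 0.0551) and GNL3 (-0.18, adjusted p = 0.0578) out of it.

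**Figure D5:**
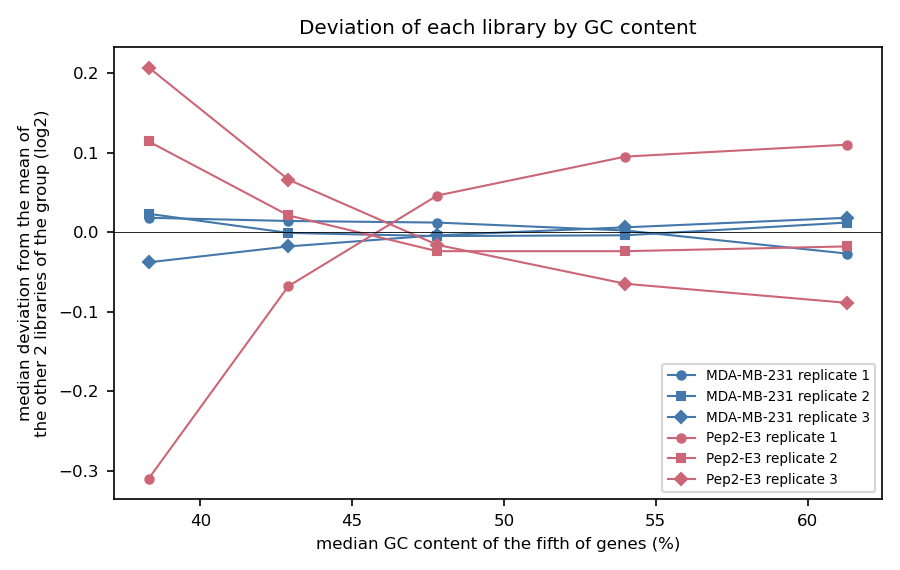
Median deviation of each library from the mean of the other 2 libraries of its group (vertical axis, log2) in 5 equal groups of genes by GC content (horizontal axis, median GC content in percent). The line of Pep2-E3 replicate 1 runs from -0.31 to 0.11, while those of the MDA-MB-231 libraries stay between -0.04 and 0.02.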

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

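The GC and length correction, leaving out the genes in chromosome blocks, and the correction with Pep2-E3 replicate 1 left out were chosen after seeing the data, and the other alternatives before. The count of changed genes differed from 4383 by over 1.5 times only when single parental libraries were left out, with a range of 2474 to 4857 over the 6 libraries left out in turn, against 1185 to 2302 genes higher and 1289 to 2555 lower. Fewer samples entered each of those fits. Without Pep2-E3 replicates 1, 2 and 3 in turn the count of changed genes was 4857, 2991 and 4261, so fewer samples alone do not account for the lower counts. Genes changed at least 2-fold numbered 557 with a pseudocount of 0.1 and 25 with a pseudocount of 5, because the pseudocount sets how much low genes can change, and 621 with limma-voom on the recovered fragments, which differs in unit, offset and weights. Gene lists called by camera numbered 11 with RLE size factors, without a filter, with the filter of 1 CPM, without mitochondrial and abundant genes and without the genes in chromosome blocks, 8 to 9 when single libraries were left out, 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 24 with fry, which asks another question. The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.04, 0.04 and -0.06, and MDA-MB-231 replicates 1 and 3 correlated best with another number. With the replicate block 2966 genes were called, 1364 of them higher and 1602 lower, 9 lists were called, and the glycolysis list (adjusted p = 0.0572) and CAD, CCNB1, GNL3, IL1B, MYC, NES, RPL8 and RPS7 among the named genes did not pass. Of the alternatives planned, the negative binomial tests and the list test built on them were not run, since the design named limma for FPKM. The recovered fragments would have allowed them. Scaling by library totals alone equals the main analysis. Depth limits genes with few fragments, such as CDH1 with 12 and 13 per group.

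Genes that did not pass and lists that camera did not call also changed sign. Of these lists, fry called YAP/TAZ targets (adjusted p = 0.0153) and the lung metastasis genes (0.0258). CD44 was 0.016 with the GC and length correction, 0.018 with the first Pep2-E3 library left out as well, and from -0.043 to 0.017 when single libraries were left out. STUB1 was -0.002 with the correction, and MKI67 ranged from -0.013 to 0.146 when single libraries were left out. The mean log2 shift of a list against all other genes changed sign as follows. With the correction it was -0.0084 for p53 targets, -0.013 for nuclear oxidative phosphorylation and -0.018 for cell migration and actin, and with the first Pep2-E3 library left out as well it was 0.0069 for integrins and -0.010 for cell migration and actin. Without the genes in chromosome blocks it was -0.0055 for mitochondrially encoded genes, -0.0026 for fatty acid synthesis and storage, 0.0029 for YAP/TAZ targets, 0.10 for the NOTCH pathway, 0.0151 for MAPK feedback and AP-1, and -0.0045 for cell migration and actin. Without a filter it was -0.0058 for mitochondrially encoded genes, -0.0037 for fatty acid synthesis and storage and -0.0073 for cell migration and actin, and with the filter of 1 CPM -3e-04 and -0.0031 for the first and last of these. With a pseudocount of 5 it was -0.0168 for mitochondrially encoded genes and -0.0013 for cell migration and actin. YAP/TAZ targets were at 0.0017 with RLE size factors, 0.0016 with upper-quartile factors, 0.038 with a pseudocount of 0.1 and 0.0368 with limma-voom, where the lung metastasis genes were at -0.0071. When single libraries were left out, the shift ranged from -0.0517 to 0.0647 for mitochondrially encoded genes, -0.0067 to 0.0362 for fatty acid synthesis and storage, -0.0144 to 0.0163 for YAP/TAZ targets, -0.0469 to 0.0014 for apoptosis, -0.0225 to 0.0016 for angiogenesis and -0.0099 to 0.0181 for cell migration and actin. The cause of these changes of sign was not tested.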

Other observations

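Genes outside the fixed lists and the naming rule, chosen after their values were seen, include further large changes in Pep2-E3. The orphan receptor gene GPRC5C rose from 0.0515 ± 0.0358 in MDA-MB-231 to 2.06 ± 0.205 FPKM in Pep2-E3 (SD, n = 3 per group) and the neuronal leucine-rich repeat gene LRRN1 from 0.0304 to 1.67 FPKM, whereas FAM133A fell from 1.70 to 0.0172 FPKM (means of 2.3 and 7.3 parental fragments in LRRN1 and GPRC5C and 1 Pep2-E3 fragment in FAM133A, limma adjusted p 0.000245, 0.000267 and 0.000260).

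Of the tests that follow, the one on parental cells mixed into a library, the one on gene order, the one on nuclear copies and the counts over other splits of the samples were chosen only after the result was seen. The other tests were written down before their own result was seen, on patterns already noticed. The test on parental cells replaced one written before its result, whose value is given beside it. The test on GC bias replaced a correlation of GC content with the deviation within genes of similar length (smallest rho 0.35), dropped after its result because the library had been seen to stand apart along GC content. The explanation tested with transcript length was first worded as length or RNA degradation and was narrowed after the result, because gene values do not show coverage along a transcript.

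Pep2-E3 replicate 1 stood apart from the other 2 Pep2-E3 libraries along GC content, and whether a GC bias accounts for this stays open: the SD of its deviation was 1.22 times the larger SD of the other 2 libraries and still 1.126 times after the GC and length correction, a value between the bounds set beforehand for and against it. Transcript length does not account for it, since within 5 groups of genes by GC content the rho with length reached at most 0.09 in size. Parental cells in the library do not account for it either, since in the 2847 genes with the lowest GC content the parental libraries lay 0.013 (log2) above the other 2 Pep2-E3 libraries and replicate 1 at -0.31. In the first test of that explanation, replicate 1 showed a median of 0.922 of the change of genes at least 2-fold higher in the other 2 libraries and 0.971 of that of lower genes, above the bound of 0.9 set against mixing, but replicates 2 and 3 gave values from 0.897 to 1.008, so the margin lay within their spread and the test was replaced. RNA degradation and biological explanations were not tested.

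Neighbouring genes are shifted together in 6 blocks in Pep2-E3. For the largest running median, chance order of genes is excluded as far as 1000 permuted orders go, since it was 0.672 in size and the highest permuted one 0.352. Over all placed genes, the ratios of neighbours correlated at 0.167, against at most 0.03 in permuted orders. The 6 blocks were chosen by exceeding 0.314, a limit from the same permuted orders, so these values do not test each block separately. A GC or length bias is argued against by the correction, after which the smallest block median was still 0.27 in size (log2). A difference in gene copy number between the 2 cell populations may account for the blocks: it predicts a shift of the whole distribution, and the interquartile range of log2 fold changes inside a block was 0.49 to 1.07 times that outside, the lowest in the block of 22 genes, in a test that bounds only a wider spread. The blocks were chosen for a shared shift in ratios from the same libraries, so this test could hardly have gone against copy number and does not favour it over other causes. No DNA data were analysed here, so a difference in copy number stays a hypothesis found and tested on the same libraries.

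Mitochondrially encoded transcripts moved apart. MT-CO1, MT-ND1 and MT-CO3 were higher (log2 fold changes 0.25 ± 0.05, 0.53 ± 0.06 and 0.49 ± 0.04, SE), and MT-CO2, MT-ND4, MT-ND4L, MT-RNR2 and MT-TP lower (-0.36 ± 0.04, -0.30 ± 0.06, -0.35 ± 0.09, -0.33 ± 0.07 and -0.24 ± 0.07). In the 5 called genes with named nuclear copies, fragments counted for the copies took up at most 0.00476% of a change. Fragments that align to a gene and its copy and were left uncounted would not appear in these values. Whether sequence shared with nuclear copies plays a part therefore stays open. A GC bias is argued against by the correction, after which 3 genes were still called higher and 4 lower, while MT-TP lost its call as its log2 fold change went to 0.07 ± 0.13 (SE). A difference in processing or stability of these transcripts between the groups stays open and could not be tested with gene values.

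With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split with the highest count in each case: 4383 changed genes against at most 0 in the other 9 splits, 2072 higher and 2311 lower against at most 0, 191 changed at least 2-fold against at most 0, and 10 lists against at most 6. Each of the other splits puts both cell populations in both groups. A difference between the populations then widens the spread within groups, so low gene counts were to be expected there. The counts therefore decide nothing about chance. Camera with the preset correlation still called 3, 6, 6, 4, 0, 0, 6, 2 and 2 lists in the other 9 splits, where 0 genes were called. A list call by this test can thus arise without any called gene, which limits what the 10 calls of the real split show.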
